A study of Arabidopsis thaliana with 16 samples.

How the data were processed

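Expression was measured in leaves of 6-week-old Arabidopsis thaliana on 16 Affymetrix arrays, 4 for each of 4 genotypes. Per the labels' protocols, total leaf RNA was extracted with a column kit and digested with DNase, and biotin-labelled cRNA was hybridised; no treatment was given. The genotypes were the wild type (WT), a line in which an artificial microRNA lowers NAA10 (amiNAA10), and a pair of T-DNA insertion lines of HYPK, called here the exon 1 line and the exon 2 line after the exon each sample's title names. The labels give no growth tray, harvest date, hybridisation batch or scan date, so no batch could be used in a fit. They also do not state whether the 4 samples of a genotype were separate plants, pools of plants or repeat preparations, and all p-values therefore measure the spread between these samples, which may be partly technical.

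The deposited table holds 1 log2 expression value per probe set and array, computed by the authors with robust multi-array averaging (RMA) per the submitters' processing notes. The array design, the software version and the probe annotation used are not given in the sources used here. RMA corrects background, forces all arrays to one distribution by quantile normalization and summarises the probes of a set with a robust fit. The quantile step was visible in the values, since the sorted columns of any pair of arrays differed by at most 0.0019 on the log2 scale; a genome-wide shift of total RNA in one genotype would be removed by it and could not be seen here. Values ran from 0.60 to 13.49 with a median of 3.17 on the log2 scale. Every one of the 27826 probe sets is named by a locus code, and no locus has more than 1 probe set. The codes were looked up in a RefSeq gene table of the assembly TAIR10.1, which was used only for gene symbols and for which loci are neighbours: 27241 probe sets matched a locus of the table, 585 did not, and 10556 have a symbol other than the locus code. Array data have no read depth; the precision of each value is limited by the 4 arrays per genotype, and the deposited table carries no detection call against background.

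The following choices were made before the data were examined: the groups, the tests, the alternatives, the gene lists and the rule for naming genes. All 16 arrays entered 1 linear model with a mean per genotype, without a block, and 6 contrasts were tested two-sided with limma's lmFit and eBayes (limma 3.58.1, R 4.3.3), with the intensity trend and the robust option off. The contrasts were amiNAA10 against WT, the mean of both HYPK lines against WT, each HYPK line against WT, the exon 1 line against the exon 2 line, and the mean of both HYPK lines against amiNAA10. P-values were adjusted over all 27826 probe sets by the Benjamini-Hochberg method, with a threshold of 0.05, and no filter was applied. The levels of NAA10, NAA15, HYPK and NAA50 were also compared with two-sided exact permutation tests, whose smallest possible p is 0.0286 for 4 arrays against 4 and 0.00202 for 8 against 4.

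Gene groups were 26 lists, all fixed by locus code except that of cytosolic ribosomal proteins. Of 457 members fixed by locus code, 10 were dropped because the reference gives the name they were listed under to another locus. A further 1 was not measured, and 446 were tested. The list of 28 cytosolic ribosomal proteins, not counted in these, was made by a rule on gene symbols. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 26 lists of a comparison, which asks whether members moved more than other genes. Camera with a correlation estimated from the data, fry, and exact permutation tests of the list mean per array were run beside it. A member was counted as having risen or fallen when its adjusted p over all genes was under 0.05, and the count adjusted over the list alone is given beside it. The named genes were the 10 largest rises and the 10 largest falls among genes with a symbol of their own, an adjusted p under 0.05 and every array of the line or lines on the same side of every WT array; for comparisons of single lines and between lines the 3 largest of each were taken by the same rule. NAA10, NAA15, HYPK and NAA50 are named throughout, and from each list members with the smallest adjusted p. Gene families grouped by symbol, and the loci named for the comparison of both HYPK lines, were chosen after their values were seen.

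The procedure was tested on simulated data with the spread of the real arrays, 27826 genes and 200 changed genes. For amiNAA10 against WT it recovered 21.2%, 73.1% and 97.0% of genes changed by 0.5, 1 and 2 on the log2 scale, with 1 false call, and for both HYPK lines against WT 22.7%, 85.1% and 97.0%, with 0 false calls by limma. Far fewer genes were changed than were called in the real data, so these shares and false calls do not carry over to the real calls. Each comparison was simulated in 1 draw, with residual arrays shuffled across genotypes, so unequal spread between genotypes was not kept. In those data, which held no effect on any list, camera with the preset correlation called 5 and 1 of the 26 lists, so a call by that test alone is weak evidence; each list called in a comparison with WT or with amiNAA10 is therefore given with the adjusted p at an estimated correlation.

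Comparisons that share the WT arrays were set against 100 simulations of unchanged groups sharing those arrays, against the overlap of independent lists, and against fits in which the 4 WT arrays were split so that each comparison had its own pair. Alternatives covered median centring and cyclic loess of the deposited values, removal of the dimmest 30% of probe sets, probe sets with 1 named gene, an intensity trend with robust variance, array weights, fits of only the groups compared, the replicate number as a block, each array left out in turn, and stricter thresholds. No sample was left out of the comparisons reported. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.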

Results

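Leaf transcripts were profiled in Arabidopsis lines that target subunits or partners of the N-terminal acetyltransferase complex NatA, which acetylates the amino terminus of many proteins as they leave the ribosome. NAA10 is the catalytic subunit of NatA, NAA15 its ribosome-binding subunit and HYPK a small protein that binds the complex; NAA50, the catalytic subunit of NatE, shares NAA15. Plants grew on soil for 6 weeks with 8.5 h of light per day at 22 °C by day and 18 °C by night and received no treatment. WT, the knockdown line amiNAA10, the HYPK exon 1 line and the HYPK exon 2 line were each measured on 4 arrays, 16 in all, with 27826 probe sets. NatA protein and acetylation were not measured, and the mean of both insertion lines is named HYPK loss after the labels only. All values are RMA expression values on the log2 scale, differences are first group minus second group, and adjusted p-values are from limma unless another test is named. Arrays of one genotype correlated with r between 0.974 and 0.990 over all probe sets, and no pair of arrays held identical values. The first principal component carried 46.4% of the variance and the second 11.1%. Replicate 4 of the exon 2 line lay at -44.3 on the first component, while the other exon 2 arrays lay between -1.87 and 15.5 and the WT arrays between 50.1 and 66.0.

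The targeted genes were examined first, because they check the sample labels. NAA10 (AT5G13780) was at 2.89 ± 0.16 (SD, n = 4) in amiNAA10 and at 4.96 ± 0.10 (SD, n = 4) in WT, a difference of -2.07 (SE 0.12) or 23.8% of the WT level (adjusted p = 2.46e-08; exact permutation p = 0.0286, the smallest 4 arrays against 4 can give). In the HYPK lines NAA10 differed from WT by -0.06 (SE 0.10, adjusted p = 0.714). HYPK (AT3G06610) was at 4.72 ± 0.14 (SD, n = 4) in the exon 1 line and at 5.66 ± 0.08 (SD, n = 4) in WT, a fall to 52.0% of the WT level (difference -0.94, SE 0.13, adjusted p = 0.000155, exact permutation p = 0.0286). In the samples labelled as the exon 2 line HYPK was at 5.40 ± 0.27 (SD, n = 4), which differed from WT by -0.26 (SE 0.13, adjusted p = 0.191, exact permutation p = 0.0571), and by -0.14 without its replicate 4 (adjusted p = 0.522). The difference between both lines was -0.68, with an exact permutation p of 0.0286 and an adjusted p over all probe sets of 0.381; without exon 2 replicate 4 it was -0.80 with an adjusted p of 0.0318. The HYPK signal thus does not check the label of the exon 2 arrays, and probe positions relative to the insertion were not used here. For the gene HYPK, amiNAA10 against WT, the difference was -0.32 (adjusted p = 0.0694, and 0.0316 without exon 2 replicate 4). NAA15 rose in amiNAA10 by 0.43 (SE 0.10, adjusted p = 0.00343) and differed by 0.14 in the HYPK lines (adjusted p = 0.293). For the gene NAA50, amiNAA10 against WT, the difference was -0.37 (adjusted p = 0.0353). That call ended without WT replicate 3 (-0.25, adjusted p = 0.130), without WT replicate 4 (adjusted p = 0.0677), without amiNAA10 replicate 1 (adjusted p = 0.0582), without amiNAA10 replicate 2 (adjusted p = 0.105) and without amiNAA10 replicate 4 (adjusted p = 0.0597). For the gene NAA50, HYPK loss (mean of both insertion lines) against WT, the difference was -0.41 (adjusted p = 0.0129), a call that ended without WT replicate 3 (-0.29, adjusted p = 0.0651).

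**Figure D1:**
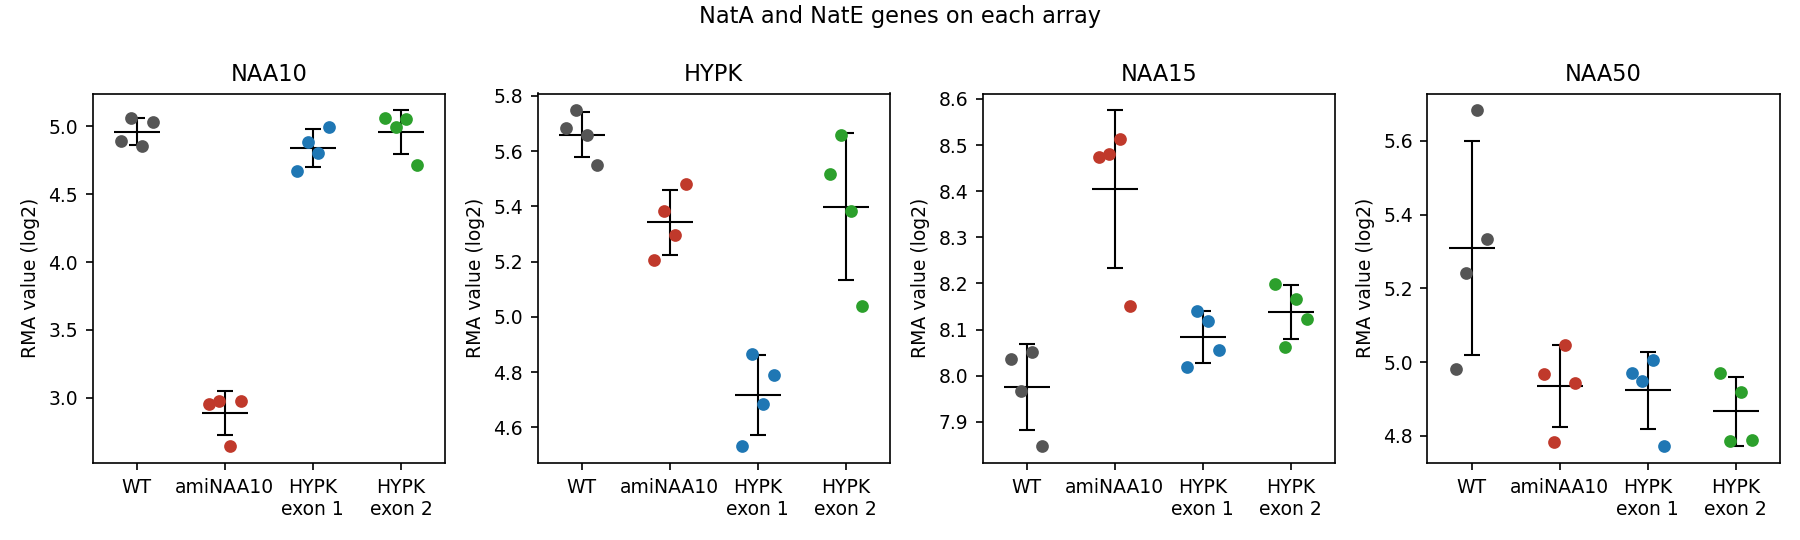
RMA expression value on the log2 scale of NAA10, HYPK, NAA15 and NAA50 on each of the 16 arrays, by genotype; points are arrays, the horizontal bar is the mean of the 4 arrays and the whiskers are its SD. NAA10 is low in amiNAA10 alone (mean 2.89), HYPK is lowest in the exon 1 line (mean 4.72), and the exon 2 line (mean 5.40) overlaps WT (mean 5.66).

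In leaves with less NAA10 transcript, PR1 and other genes of salicylic acid defence rose and genes of photosynthesis fell. Among the genes named by the rule, CAX3 rose most, and ARR15 and CSLA01 fell most. CAX3, a vacuolar calcium/proton exchanger, was 55.4-fold higher than in WT (log2 5.79, SE 0.31, adjusted p = 1.51e-08, n = 4 per group), and PR1, a secreted marker protein of salicylic acid signalling, was higher by 5.36 (SE 0.92, adjusted p = 0.000333). ARR15 and ARR6, response regulators that are induced by and restrain cytokinin signalling, fell by 4.48 (SE 0.51, adjusted p = 1.12e-05) and by 3.81 (SE 0.27, adjusted p = 2.51e-07). CSLA01, of the cellulose synthase-like family, fell by 4.43 (SE 0.41, adjusted p = 2.07e-06). The other genes among the 10 largest rises were a chitinase-like gene (AT2G43570, 5.45), the abscisic acid transporter gene ABCG40 (5.22), the receptor-like protein gene RLP41 (5.06), the nitrilase gene NIT2 (4.99), the calmodulin-like gene CML41 (4.77) and the cysteine-rich receptor-like kinase genes CRK6 (4.70), CRK23 (4.49) and CRK7 (4.48). The largest falls further included ATSDI1 (-3.38), known from sulphur deficiency, JMT (-3.35), which methylates jasmonic acid, TBL26 (-3.25), the auxin-responsive SAUR29 (-3.08), the protein kinase gene CIPK20 (-3.05), the carbonic anhydrase gene ACA1 (-2.91) and FSD1 (-2.86), an iron superoxide dismutase. By the rule for naming, each of these genes was on one side of all 4 WT arrays in all 4 amiNAA10 arrays. Here and below, a change may be a lower bound where 1 of the 2 means compared lay under 1.83. That level bounds the dimmest 30% of probe sets and is not a measured background, so means slightly above it may be affected too. A mean under 1.83 entered the changes of NIT2 and CSLA01 in amiNAA10, and of BCS1 and CYP71A13 against WT. Such a mean also entered that of PDF1 between the HYPK lines and amiNAA10, and that of AT3G06600 in the exon 2 line.

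Of the 27 measured genes of salicylic acid defence, 20 rose in amiNAA10 (22 adjusted over the list alone), with a mean difference of 2.03, among them ACD6 (2.52, SE 0.20), a membrane protein that promotes salicylic acid accumulation, and DMR6 (3.35, SE 0.35), which hydroxylates salicylic acid. Camera with the preset correlation gave this list an adjusted p of 7.68e-11, against an adjusted p = 0.349 with an estimated correlation. Of 19 genes of the unfolded protein response of the endoplasmic reticulum, 11 rose (16 adjusted over the list alone), including the calreticulin gene CRT3 (2.11, SE 0.27) and the stress sensor gene BZIP28 (0.59, SE 0.13). Their mean was 1.08 (adjusted p = 2.96e-05, and adjusted p = 0.490 with an estimated correlation). In the N-degron and ubiquitin pathway 11 of 22 members rose (11 adjusted over the list alone), including the polyubiquitin gene UBQ10 (0.94, SE 0.11). Their mean was 0.40 (adjusted p = 0.000326, and adjusted p = 0.212 with an estimated correlation). Of 51 genes of the 26S proteasome, 12 rose (9 adjusted over the list alone), such as the lid subunit gene AT4G24820 (0.63, SE 0.13) and the base subunit gene AT2G32730 (0.54, SE 0.11). The list mean was 0.18 (adjusted p = 0.00736, and adjusted p = 0.613 with an estimated correlation). Fry did not call this list (adjusted p = 0.0978). Autophagy genes rose in 9 of 18 cases (9 adjusted over the list alone), led by APG7 (1.08, SE 0.15) and ATG2 (1.09, SE 0.17), with a mean of 0.54, an adjusted p of 0.000326 and an adjusted p = 0.349 with an estimated correlation. Of 16 senescence genes 8 rose and 1 fell (8 and 1 adjusted over the list alone); SEN1 rose by 2.73 (SE 0.29) and the asparagine synthetase gene ASN1 by 1.91 (SE 0.22). The members averaged 0.99 (adjusted p = 0.000317, and adjusted p = 0.212 with an estimated correlation). The mitochondrial stress response had 6 rises and 1 fall among 13 members (6 and 1 adjusted over the list alone), with BCS1, an outer membrane protein gene, at 1.60 (SE 0.28) and the NADH dehydrogenase gene NDA1 at -1.34 (SE 0.20). These genes had a mean of 0.84 (adjusted p = 0.0118, and adjusted p = 0.349 with an estimated correlation). The call ended without the dimmest 30% of probe sets (adjusted p = 0.0912).

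Photosynthesis genes fell in 44 of 47 cases in amiNAA10 (45 adjusted over the list alone), with a mean of -0.80 and an adjusted p of 1.05e-21, against an adjusted p = 0.212 with an estimated correlation. PSBP-1, of the oxygen-evolving complex, fell by 1.21 (SE 0.12) and RBCS2B, a small subunit of Rubisco, by 2.15 (SE 0.22). Vascular and guard cell markers fell alongside, while epidermis markers were not called. Falls were found in 7 of 11 vascular markers (7 adjusted over the list alone), such as the phloem regulator gene APL (-1.16, SE 0.11) and the sulphate transporter gene SULTR2;1 (-1.29, SE 0.14). The mean difference was -0.67 (adjusted p = 0.000169, and adjusted p = 0.0785 with an estimated correlation). Falls were also called in 4 of 6 guard cell and myrosin cell markers (4 adjusted over the list alone), such as the anion channel gene OZS1 (-1.43, SE 0.19) and the potassium channel gene KAT1 (-0.91, SE 0.13). Their mean was -0.67 (adjusted p = 0.00318, and adjusted p = 0.222 with an estimated correlation). Aliphatic glucosinolate and flavonoid genes were lower. Indole glucosinolate and camalexin genes moved both ways, with 3 rises and 3 falls among 9, and were not called as a list. Of 16 aliphatic glucosinolate genes 12 fell and 1 rose (12 and 1 adjusted over the list alone), with the sulphotransferase gene SOT18 at -1.24 (SE 0.15). The list mean was -0.76 (adjusted p = 7.84e-05, and adjusted p = 0.349 with an estimated correlation). Of 13 anthocyanin and flavonoid genes 7 fell (8 adjusted over the list alone), with the hydroxylase gene F3H at -1.94 (SE 0.18). The members averaged -0.77 (adjusted p = 0.000920, and adjusted p = 0.222 with an estimated correlation). Jasmonate response genes fell in 9 of 22 cases (10 adjusted over the list alone), among them JMT and the regulator gene MYC2 (-1.71, SE 0.27), although the exact permutation test of the list mean had an adjusted p of 0.165. These genes had a mean of -0.70 (adjusted p = 0.00322, and adjusted p = 0.592 with an estimated correlation). For the list jasmonate response, amiNAA10 against WT, the mean was -0.44 without amiNAA10 replicate 3 and -0.46 without WT replicate 4.

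The remaining lists were not called in amiNAA10 by camera with the preset correlation. Among them, fry called N-terminal acetyltransferases (adjusted p = 0.000148), methionine aminopeptidases (0.0274), hypoxia response (0.00423) and root markers (0.0111). Exact permutation of list means called these and heat shock and cytosolic chaperones, each at an adjusted p of 0.0437. The adjusted p-values of lists below are from camera. Heat shock and cytosolic chaperone genes rose in 5 of 28 cases (4 adjusted over the list alone; adjusted p = 0.0593), with HSP81-2 at 1.03 and HSP90.1 at 2.39. Without amiNAA10 replicate 1 or 4 the list was called (adjusted p = 0.0144 and 0.0186), while over all arrays it had an adjusted p = 0.592 with an estimated correlation. Much of its difference came from amiNAA10 replicate 2, where heat shock and cytosolic chaperone genes averaged 4.26. The other amiNAA10 arrays were at 3.29 to 3.58, and WT arrays were at most at 3.27. Of 27 abscisic acid and drought genes 2 rose and 8 fell (3 and 10 adjusted over the list alone; adjusted p = 0.304), with RAB18 at -1.17 and ABF3 at -0.52. Hypoxia genes showed 4 rises and 2 falls in 23 (the same counts adjusted over the list alone; adjusted p = 0.508), AlaAT1 being at 1.27. Among 19 circadian clock genes 5 rose and 4 fell (5 and 4 adjusted over the list alone; adjusted p = 0.802, mean -0.07, median 0.08), with CDF1 at -1.65 and RVE1 at -1.95. Indole glucosinolate and camalexin genes had 3 rises and 3 falls in 9 (3 and 3 adjusted over the list alone; adjusted p = 0.854, mean 0.19, median -0.01), with CYP79B3 at -2.11 and MYB34 at -2.49. For rapid stress and handling genes the counts were 3 and 1 of 16 (3 and 1 adjusted over the list alone; adjusted p = 0.658, mean 0.19, median -0.02), TCH3 being at 1.47 and TCH2 at -1.05. Cytosolic ribosomal protein genes had 3 rises and 4 falls in 28 (3 and 4 adjusted over the list alone; adjusted p = 0.802), RPL3B being at -0.68. N-terminal acetyltransferase genes other than those above gave, with them, 3 rises and 2 falls in 11 (3 and 3 adjusted over the list alone; adjusted p = 0.790). Of 4 methionine aminopeptidase genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.508), MAP2A being at 1.34 and MAP1D at -0.73. Among markers of other cells, 1 of 12 cell division genes rose (0 adjusted over the list alone; adjusted p = 0.508). Of 7 epidermis markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.790, mean 0.05, median -0.10), PDF1, a gene of the shoot epidermis, being at 3.39 and CER1, of cuticular wax synthesis, at -2.14. Of 2 root markers PYK10 rose (1.86; 1 adjusted over the list alone; list adjusted p = 0.219). Of 7 flowering and floral markers 1 fell (1 adjusted over the list alone; adjusted p = 0.802).

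Over all probe sets limma called 8549 of 27826 (30.7%) between amiNAA10 and WT. These were 4274 higher and 4275 lower, of which 1171 and 1089 changed at least 2-fold. In 30.6% of probe sets the 4 amiNAA10 arrays lay entirely above or below the 4 WT arrays, against 2.86% by chance. Of the 26 lists, camera with the preset correlation called 13, 7 up and 6 down, fry 16, exact permutation of list means 17, and camera with an estimated correlation 0. With 0 lists called at an estimated correlation, the group statements only describe counts of members, which are correlated genes read on the same arrays. Each count stands against the share over all probe sets. That share was 30.7% here and 22.7% in the HYPK lines, about equally higher and lower.

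**Figure D2:**
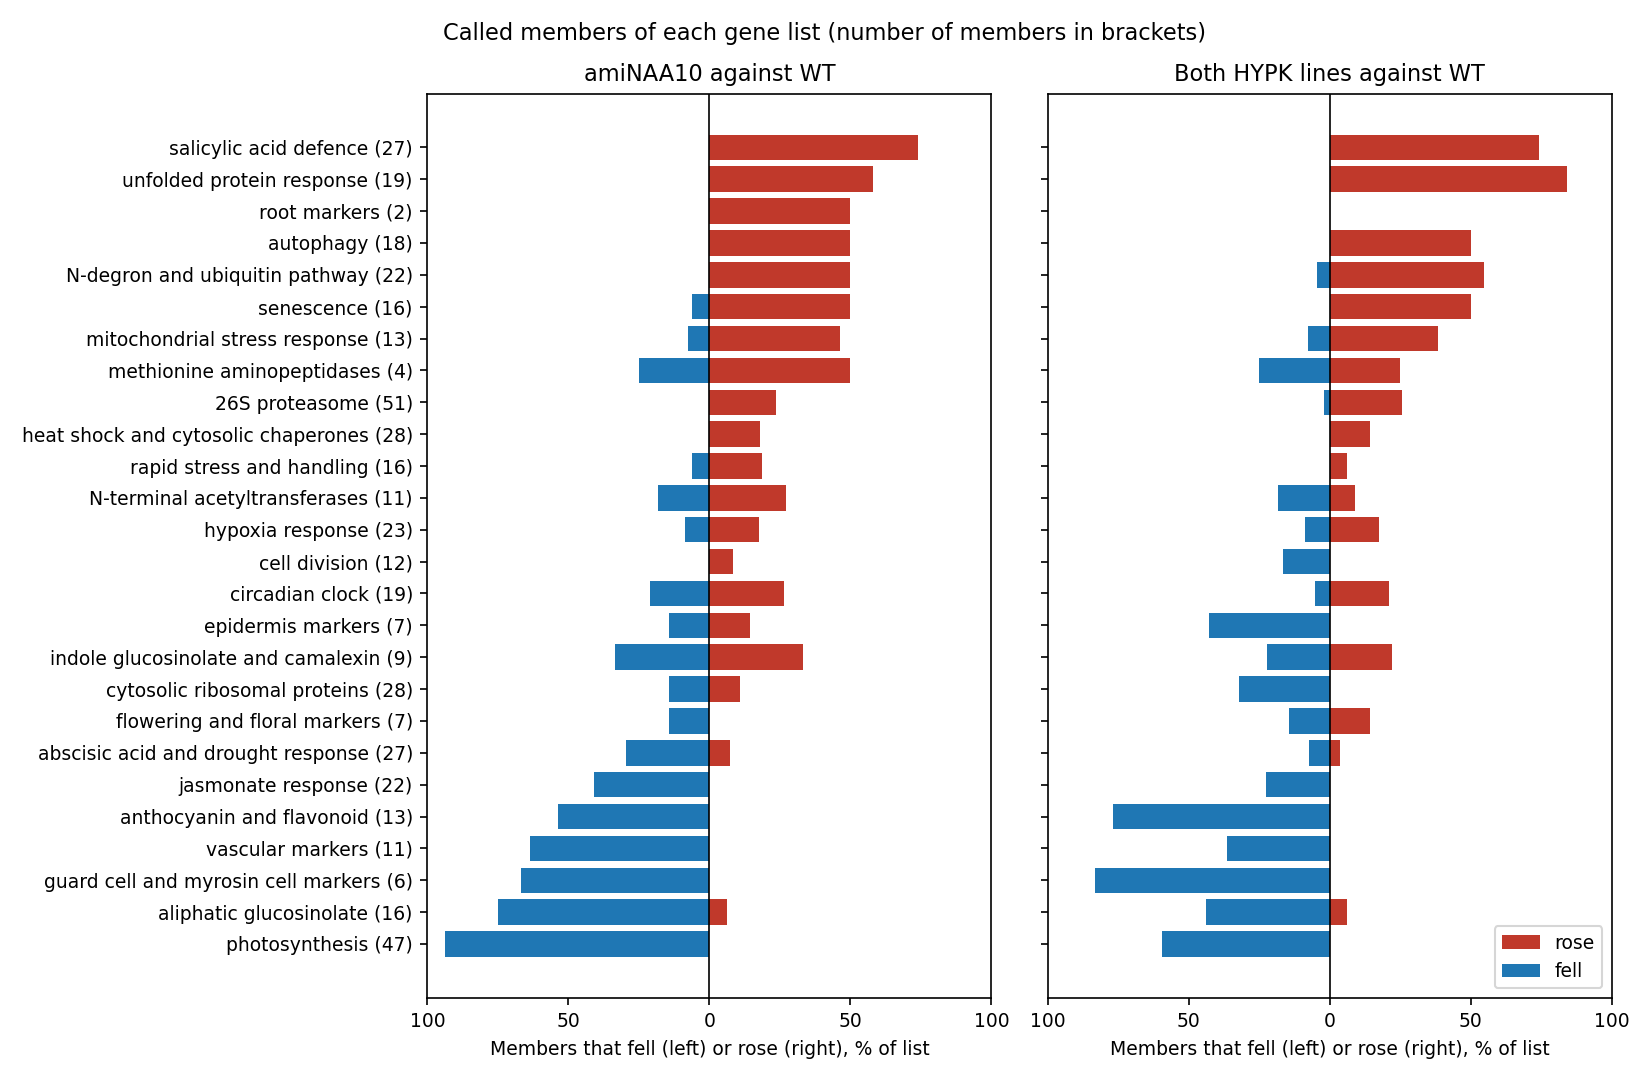
Share of the measured members of each of 26 gene lists that rose (red, right) or fell (blue, left) at an adjusted p under 0.05 in amiNAA10 against WT (left panel) and in both HYPK lines against WT (right panel); the number of members stands in brackets and both sides of the horizontal axis are percent of the list. Salicylic acid defence had 20 rises among 27 members in both panels, and photosynthesis 44 falls of 47 in amiNAA10 and 28 in the HYPK lines.

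The HYPK insertion lines were compared with WT to see whether lines of the auxiliary protein resemble the knockdown of the catalytic subunit. The HYPK signal itself was called lower in the exon 1 line and not in the exon 2 line. In the mean of both insertion lines CAX3 was 42.7-fold higher than in WT (log2 5.42, SE 0.26, adjusted p = 8.83e-09, n = 8 against 4) and PR1 24.4-fold higher (4.61, SE 0.80, adjusted p = 0.000704). CSLA01 fell by 4.28 (SE 0.36, adjusted p = 1.50e-06), CER1 by 2.71 (SE 0.37, adjusted p = 0.000115) and EXPB3, a cell wall-loosening expansin, by 2.66 (SE 0.20, adjusted p = 4.70e-07). The other genes of the 10 largest rises were the chitinase-like gene AT2G43570 (4.38), RLP41 (4.28), CRK23 (3.96), CML41 (3.95), RLP38 (3.75), the thaumatin-like defence gene PR5 (3.74), CRK6 (3.69) and CRK7 (3.68). The other largest falls were ARR15 (-2.76), FSD1 (-2.53), the beta-amylase gene BAM5 (-2.47), MRD1 (-2.37), the carboxypeptidase gene BRS1 (-2.15), the beta-glucosidase gene BGLU1 (-2.12) and ATSDI1 (-2.04). Each named gene was on one side of all 4 WT arrays in all 8 arrays of the HYPK lines.

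Salicylic acid defence genes rose in 20 of 27 cases in the HYPK lines (23 adjusted over the list alone), with a mean of 1.89, and ACD6 was at 2.51 (SE 0.17) and DMR6 at 3.02 (SE 0.30). The list had an adjusted p of 1.33e-14, and adjusted p = 0.246 with an estimated correlation. Exon 2 replicate 4 had the highest mean of these genes on any array, 7.28 against 5.37 to 5.41 on the other exon 2 arrays, and without it the count that passed was also 20. Of 19 unfolded protein response genes 16 rose (17 adjusted over the list alone), with CRT3 at 1.72 (SE 0.23) and the chaperone gene BIP1 at 1.79 (SE 0.35), and 15 rose without that array. The mean difference was 1.15 (adjusted p = 2.99e-08, and adjusted p = 0.334 with an estimated correlation). In the N-degron and ubiquitin pathway 12 of 22 members rose and 1 fell (13 and 1 adjusted over the list alone), with BIG, a very large protein of that pathway and of auxin transport, at 0.69 (SE 0.10) and UBQ4 at 0.80 (SE 0.12). Their mean was 0.34 (adjusted p = 0.000134, and adjusted p = 0.146 with an estimated correlation). The 26S proteasome had 13 rises and 1 fall among 51 genes (13 and 2 adjusted over the list alone), led by the ubiquitin receptor gene RPN13 (0.42, SE 0.10). The list mean was 0.18 (adjusted p = 0.00104, and adjusted p = 0.582 with an estimated correlation). Of 18 autophagy genes 9 rose (9 adjusted over the list alone), such as APG7 (0.79, SE 0.13). The members averaged 0.42 (adjusted p = 0.000167, and adjusted p = 0.334 with an estimated correlation). Senescence genes rose in 8 of 16 cases (9 rises and 2 falls adjusted over the list alone), ASN1 by 1.74 (SE 0.19) and SEN1 by 2.21 (SE 0.25). These genes had a mean of 0.70 (adjusted p = 0.000161, and adjusted p = 0.146 with an estimated correlation). The mitochondrial stress response had 5 rises and 1 fall in 13 (5 and 1 adjusted over the list alone), BCS1 and NDB2 both being at 1.46. The mean difference was 0.57 (adjusted p = 0.0373, and adjusted p = 0.398 with an estimated correlation). The call ended without WT replicate 1 (adjusted p = 0.0550) or 3 (0.0501), or without the dimmest 30% of probe sets (0.0988).

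Photosynthesis genes fell in 28 of 47 cases in the HYPK lines (33 adjusted over the list alone), including PSBP-1 (-0.70, SE 0.10) and PSBQ-2 (-0.54, SE 0.09). Their mean was -0.38 (adjusted p = 2.26e-11, and adjusted p = 0.334 with an estimated correlation). Guard cell and myrosin cell markers fell with them in 5 of 6 cases (5 adjusted over the list alone), KAT1 by 0.71 (SE 0.11) and OZS1 by 1.06 (SE 0.17). The list mean was -0.61 (adjusted p = 0.000134, and adjusted p = 0.146 with an estimated correlation). So did 4 of 11 vascular markers (4 adjusted over the list alone), SULTR2;1 by 0.89 (SE 0.12) and the secondary wall cellulose synthase gene CESA4 by 1.03 (SE 0.18). The members averaged -0.35 (adjusted p = 0.00753, and adjusted p = 0.146 with an estimated correlation). Of 13 anthocyanin and flavonoid genes 10 fell (12 adjusted over the list alone), F3H by 1.33 (SE 0.16). These genes had a mean of -0.95 (adjusted p = 4.46e-07, and adjusted p = 0.146 with an estimated correlation). Of 16 aliphatic glucosinolate genes 7 fell and 1 rose (9 and 1 adjusted over the list alone); BCAT3 was at -0.96 (SE 0.16) and IMS2, a chain-elongation synthase gene, at 1.79 (SE 0.25). The mean difference was -0.34 (adjusted p = 0.00291, and adjusted p = 0.517 with an estimated correlation). Cytosolic ribosomal protein genes fell in 9 of 28 cases (9 adjusted over the list alone), RPS15A by 0.72 (SE 0.12) and RPL24A by 0.87 (SE 0.15), and 6 fell without exon 2 replicate 4. Their mean was -0.27 (adjusted p = 0.000849, and adjusted p = 0.381 with an estimated correlation). Jasmonate response genes fell in 5 of 22 cases (5 adjusted over the list alone; mean -0.29), JMT by 1.93 (SE 0.20). The list had an adjusted p of 0.04995, an adjusted p = 0.672 with an estimated correlation, and an adjusted exact permutation p of 0.480. That call ended without amiNAA10 replicate 1 or 2, exon 1 replicate 1 or 3, exon 2 replicate 1 or 4, or WT replicate 1 or 4, with adjusted p from 0.0532 to 0.453, and without the dimmest 30% of probe sets (0.189). Its mean was -0.04 without WT replicate 4, -0.18 without exon 1 replicate 1 or exon 2 replicate 1, and -0.43 without WT replicate 3, so single arrays carried much of it. Of 7 epidermis markers 3 fell (4 falls and 1 rise adjusted over the list alone). The list mean was -0.62 (adjusted p = 0.04995, and adjusted p = 0.441 with an estimated correlation). The call ended without amiNAA10 replicate 2, exon 1 replicate 2 or 3, exon 2 replicate 3 or 4, or WT replicate 1, 2 or 4, with adjusted p from 0.0527 to 0.0791, and without the dimmest 30% of probe sets (0.0985).

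The other lists were not called in the HYPK lines by camera with the preset correlation. Exact permutation of list means called 16 lists, of which 12 were also called by that camera test. Heat shock and cytosolic chaperone genes rose in 4 of 28 cases (0 adjusted over the list alone; adjusted p = 0.196). Hypoxia genes had 4 rises and 2 falls in 23 (5 and 2 adjusted over the list alone; adjusted p = 0.650), with AlaAT1 at 0.80. Abscisic acid and drought genes had 1 rise and 2 falls in 27 (1 and 2 adjusted over the list alone; adjusted p = 0.993, mean 0.03, median -0.05), with the phosphatase gene HAB1 at 0.90 and COR15A at -1.62. Clock genes had 4 rises and 1 fall in 19 (4 and 1 adjusted over the list alone; adjusted p = 0.469), LHY being at 0.32 and RVE1 at -0.88. Indole glucosinolate and camalexin genes had 2 and 2 in 9 (3 and 3 adjusted over the list alone; adjusted p = 0.849, mean 0.14, median -0.25), CYP79B3 being at -1.32 and CYP71A13 at 2.48. Rapid stress and handling genes had 1 rise in 16, that of TCH3 at 0.96 (1 adjusted over the list alone; adjusted p = 0.237). Cell division genes had 2 falls in 12 (1 adjusted over the list alone and 1 without exon 2 replicate 4; adjusted p = 0.332), and flowering and floral markers 1 rise and 1 fall in 7 (1 and 1 adjusted over the list alone, and the fall alone without exon 2 replicate 4; adjusted p = 0.914). Of the N-terminal acetyltransferase genes 1 rose and 2 fell in 11 (2 and 2 adjusted over the list alone; adjusted p = 0.941, mean -0.02, median 0.10). Of the methionine aminopeptidase genes 1 rose and 1 fell in 4 (2 and 1 adjusted over the list alone; adjusted p = 0.582), MAP2A being at 1.17. Of 2 root markers neither passed limma's test (0 adjusted over the list alone; adjusted p = 0.592), PYK10 being at -0.09.

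Limma called 6317 of 27826 probe sets (22.7%) between the HYPK lines and WT, 3111 higher and 3206 lower, of which 622 and 397 changed at least 2-fold, so the share of rises was 61.0% among the larger changes and 49.2% among all. All 8 HYPK arrays lay above or below all 4 WT arrays in 12.4% of probe sets, against 0.404% by chance. Without exon 2 replicate 4 the count was 5562. Of the 26 lists, camera with the preset correlation called 15, 7 up and 8 down (13 without exon 2 replicate 4), fry 13, exact permutation of list means 16, and camera with an estimated correlation 0.

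**Figure D3:**
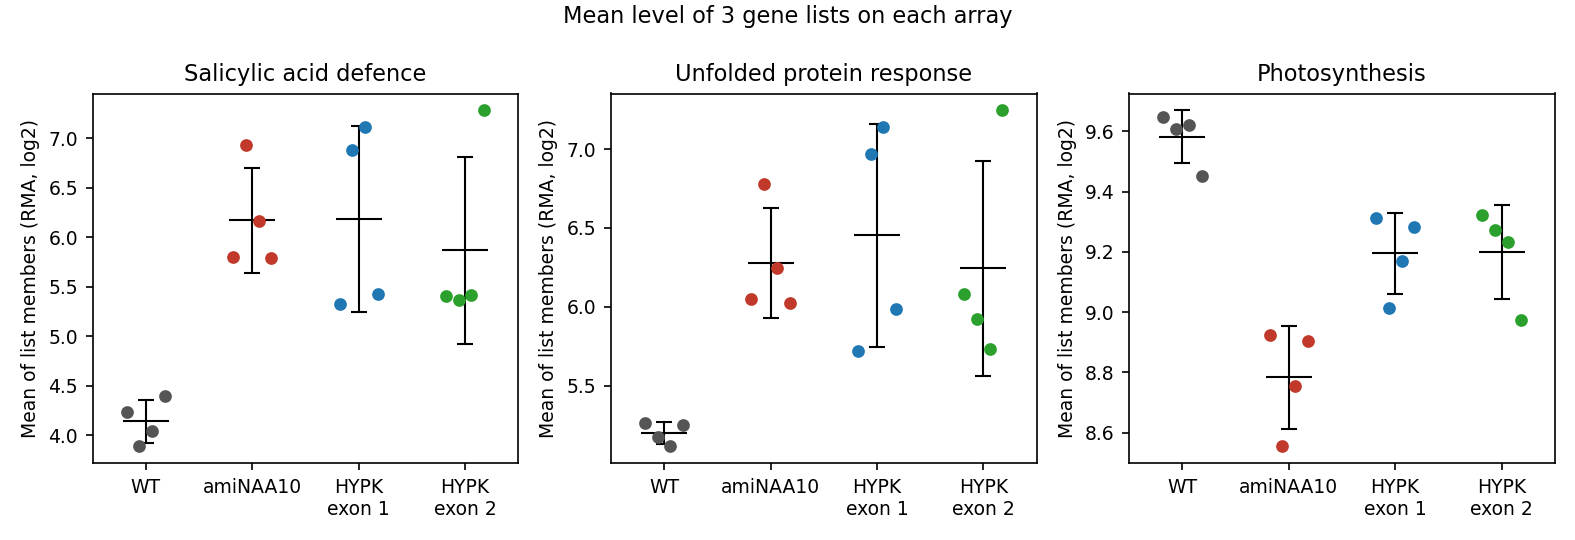
Mean RMA expression value on the log2 scale of the members of 3 gene lists on each of the 16 arrays; points are arrays, the horizontal bar is the mean of the 4 arrays of a genotype and the whiskers are its SD. Salicylic acid defence genes lie between 3.89 and 4.40 in WT and above 5.3 on every array of the other lines, and exon 2 replicate 4 reaches 7.28.

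Each insertion line taken alone showed the rises of CAX3 and the chitinase-like gene AT2G43570 and the fall of CSLA01. In the exon 1 line CAX3 was at 5.65 (SE 0.31), PR1 at 5.63 (SE 0.92) and AT2G43570 at 4.74 (SE 0.48) against WT, and CSLA01 was at -4.37 (SE 0.41), CER1 at -3.20 (SE 0.42) and EXPB3 at -2.74 (SE 0.23), with adjusted p-values from 4.45e-08 to 0.000615. In the samples labelled as the exon 2 line CAX3 was at 5.18 (SE 0.31), AT2G43570 at 4.01 (SE 0.48) and RLP41 at 3.92 (SE 0.50), and CSLA01 was at -4.19 (SE 0.41), ARR15 at -2.85 (SE 0.51) and FSD1 at -2.69 (SE 0.28), with adjusted p-values from 1.75e-07 to 0.00212. Limma called 5448 probe sets in the exon 1 line (2697 higher, 2751 lower) and 3852 in the exon 2 line (1955 higher, 1897 lower). The exon 2 count was 2097 without its replicate 4 and 2477 in a fit of only that line and WT.

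The direct comparison of both insertion lines asks whether they differ from each other. AT4G10695 differed by -2.27 (exon 1 minus exon 2, SE 0.20, adjusted p = 5.43e-05) and AT3G06600, the locus next to HYPK, by -1.98 (SE 0.15, adjusted p = 1.23e-05); both loci are named because of their values. Each was at its WT level within error in the exon 1 line (-0.23, adjusted p = 0.488, and -0.04, adjusted p = 0.890) and rose in the exon 2 line (2.04, adjusted p = 1.89e-05, and 1.94, adjusted p = 3.15e-06). These were the 2 probe sets limma called, with 0 higher in the exon 1 line, while 1220 probe sets had an unadjusted p under 0.05. Of the lists, camera with the preset correlation called jasmonate response (0.29, adjusted p = 0.0292), anthocyanin and flavonoid (-0.26, adjusted p = 0.0112), rapid stress and handling (-0.29, adjusted p = 0.00574) and guard cell and myrosin cell markers (-0.17, adjusted p = 0.0292), none of whose members passed limma's test. The smallest adjusted p was 0.698 with an estimated correlation, and fry and exact permutation each called 0 lists. Single arrays moved some of these means. For rapid stress and handling, exon 2 replicate 2 was at 5.15 and the other exon 2 arrays at 4.27 to 4.57. Anthocyanin and flavonoid was at 3.36 on exon 2 replicate 1 and at 2.78 to 3.18 on the others of that line. Jasmonate response was at 4.93 on exon 1 replicate 1 and at 5.62 to 6.12 on the other exon 1 arrays, which lessened its difference. Across probe sets the changes of both lines against WT correlated with r = 0.926. That compares with a mean of 0.499 and a range of -0.00248 to 0.766 in simulations of unchanged groups sharing the WT arrays, and 0.740 to 0.800 when each line was set against its own pair of WT arrays. Genes are not independent replicates, so r describes these arrays. The covariance was 0.200 against a simulated 0.0208, a difference of 0.179. Both lines had 1657 probe sets called higher, against 189 for independent lists, and 1586 called lower, against 188, and 0 called in opposite directions by limma. Part of this excess may come from the shared WT arrays, since the overlap was not counted in the simulations or with split WT arrays. The median change in the exon 2 line was 0.820 times that in the exon 1 line over the probe sets called in the latter, of which 99.7% had the same sign. Choosing probe sets by the exon 1 change lowers this ratio, and the shared WT arrays raise the agreement in sign. Neither figure was computed for unchanged groups.

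The HYPK lines were also compared directly with amiNAA10, in which WT cancels. Limma called 10.2% of all probe sets in this comparison, and each count of members stands against that share. Photosynthesis genes were higher in the HYPK lines than in amiNAA10 in 29 of 47 cases (40 adjusted over the list alone), RBCS2B by 1.37 (SE 0.19) and LHCB2.1, of the light-harvesting antenna, by 0.65 (SE 0.13). The members averaged 0.41 (adjusted p = 2.50e-20, and adjusted p = 0.444 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 9 of 28 cases (12 adjusted over the list alone), including RPS6 (-0.53, SE 0.12) and EMB3010 (-0.47, SE 0.11). These genes had a mean of -0.29 (adjusted p = 5.79e-06, and adjusted p = 0.444 with an estimated correlation). PDF1 was 12.5-fold lower in the HYPK lines (-3.65, SE 0.37, adjusted p = 4.52e-05), which may be a lower bound. Its level was 5.40 ± 1.37 (SD, n = 4) in amiNAA10 and 2.01 ± 0.10 (SD, n = 4) in WT. The germin-like gene GER3 (-3.01, SE 0.43, adjusted p = 0.000573) and the lipase gene LTL1 (-2.93, SE 0.42, adjusted p = 0.000557) were also lower. The microRNA gene MIR841a (2.60, SE 0.23, adjusted p = 1.53e-05), CIPK20 (2.19, SE 0.34, adjusted p = 0.000965) and LEA3 (1.92, SE 0.22, adjusted p = 0.000142) were higher. Vascular markers were higher in 4 of 11 cases (5 adjusted over the list alone), PP2-A1 by 0.72 (SE 0.08). The mean difference was 0.32 (adjusted p = 0.00109, and adjusted p = 0.149 with an estimated correlation). Aliphatic glucosinolate genes were higher in 5 of 16 (7 rises and 1 fall adjusted over the list alone), SOT18 by 0.90 (SE 0.13). Their mean was 0.43 (adjusted p = 0.00105, and adjusted p = 0.784 with an estimated correlation). Jasmonate response genes were higher in 3 of 22 (5 adjusted over the list alone), JMT by 1.42 (SE 0.20). The list mean was 0.41 (adjusted p = 0.0136, and adjusted p = 0.792 with an estimated correlation). Much of it came from amiNAA10 replicate 3, where jasmonate response genes averaged 4.26, against 5.04 to 5.61 on the other amiNAA10 arrays. Cell division genes were lower in 3 of 12 cases (3 adjusted over the list alone), CYCD3;1, a D-type cyclin gene, by -1.74 (SE 0.30) and SYP111, of cell plate formation, by -0.73 (SE 0.20). The members averaged -0.37 (adjusted p = 0.0269, and adjusted p = 0.784 with an estimated correlation). Much of this came from amiNAA10 replicates 2 and 3, with cell division genes at 3.44 on replicate 2 and higher on replicate 3. Replicate 1 was at 3.02, and replicate 4, at 2.76, lay within the range of the HYPK arrays (2.69 to 2.99).

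Salicylic acid defence genes had 0 of 27 members called between the HYPK lines and amiNAA10 by limma (0 adjusted over the list alone; mean -0.14, camera adjusted p = 0.466), and 1 of 19 unfolded protein response genes, BZIP28 (-0.50, SE 0.11), was lower (1 adjusted over the list alone; mean 0.07, adjusted p = 0.930). Limma called 2850 probe sets (1487 higher and 1363 lower in the HYPK lines), of which 133 and 171 differed at least 2-fold. The count was 1387 without amiNAA10 replicate 2 and 1496 without amiNAA10 replicate 3, and camera with the preset correlation called 6 lists, fry 4 and exact permutation 6, with 0 at an estimated correlation.

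Across probe sets the changes in amiNAA10 and in the HYPK lines correlated with r = 0.865; as before, genes are not independent replicates. Simulated unchanged groups that shared the WT arrays gave a mean r of 0.565 and a range of 0.0482 to 0.817, and the observed r was 0.727 to 0.787 when each comparison had its own pair of WT arrays. The covariance was 0.241 against a simulated 0.0199, a difference of 0.221. CAX3, PR1 and CSLA01 were at the extremes of both comparisons. There were 2441 probe sets called higher in both, against 478 for independent lists, 2352 called lower in both, against 493, and 12 called in opposite directions. The shared WT arrays raise such an overlap even without a common effect, and it was not counted in the simulations or with split WT arrays. Over the 8549 probe sets called in amiNAA10, 95.6% had the same sign in the HYPK lines, where the median change was 0.616 times as large. Choosing probe sets by their amiNAA10 change lowers such a ratio, and the shared WT arrays raise the agreement in sign. Neither figure was computed for unchanged groups, so the ratio does not measure a weaker effect of HYPK loss.

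**Figure D4:**
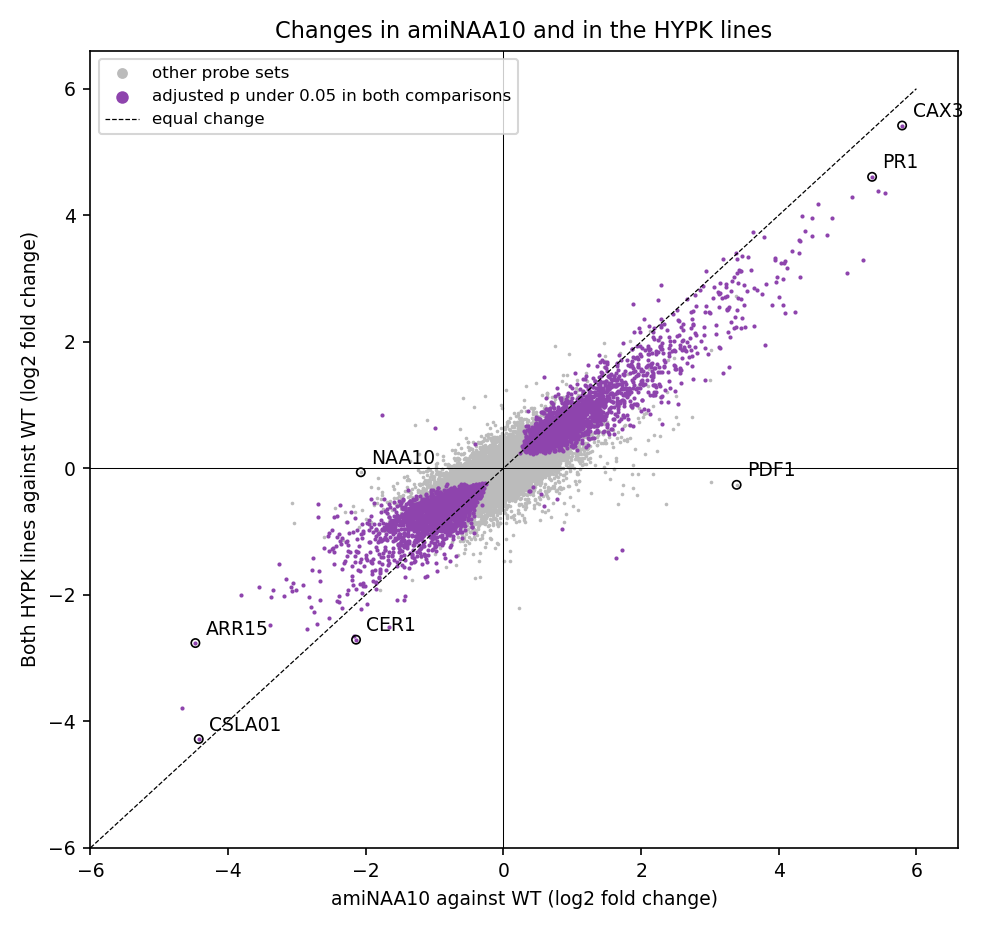
Log2 fold change against WT of every probe set in amiNAA10 (horizontal axis) and in the mean of both HYPK lines (vertical axis); purple points had an adjusted p under 0.05 in both comparisons, grey points did not, and the dashed line marks equal change. CAX3 lies at 5.79 and 5.42 and CSLA01 at -4.43 and -4.28, while NAA10 (-2.07 and -0.06) and PDF1 (3.39 in amiNAA10) lie near the horizontal axis.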

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

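The tests of wild-type admixture, of probe position and of the loci around HYPK were chosen only after the results were seen.

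The HYPK signal in the samples labelled as the exon 2 line was -0.26 from WT, and -0.14 without replicate 4 (limma adjusted p = 0.522), against -0.94 in the exon 1 line. If these were wild-type arrays, they should lie nearer to WT, but 0 of 4 lay nearer to the WT mean than to the exon 1 mean over all probe sets (distances of 70.1, 70.2, 77.5 and 114 to WT against 61.1, 57.4, 44.6 and 53.0 to exon 1). If wild-type plants had been mixed in, changes should shrink roughly as HYPK does. However, the median ratio of exon 2 to exon 1 changes was 0.855 over 8549 probe sets, against 0.277 for HYPK. It ran from 0.708 to 0.940 with single exon 2 arrays left out. On the log2 scale mixing would not shrink every change by one factor, and the shared WT arrays pull this ratio towards equal change. The comparison is therefore approximate. Probes outside the disrupted part of the transcript could leave a change as small as -0.26, and this remains open because probe positions were not used. The HYPK level therefore does not check the exon 2 label.

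AT3G06600, the locus next to HYPK, differed by -1.98 between the exon 1 and exon 2 lines and AT4G10695 by -2.27. For a local effect of the insertion, other loci close by should differ too, and the 4 other loci nearest to HYPK were at percentile 99.96 of such windows by mean absolute moderated t, which may reflect the insertion. Most of this came from AT3G06590 (-0.77, limma adjusted p = 0.228), while AT3G06620 (-0.31), AT3G06630 (-0.22) and GALK (-0.10) differed less. Coincidence of position was set aside on this same comparison. It predicts that these 4 loci differ no more than others, and 0.0367% of windows around other loci differed as much. Those windows could lie close to HYPK and hold AT3G06600, which was left out only of the window of HYPK, so percentile and percentage are approximate. AT4G10695 lies on another chromosome and its rise was not explained.

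Salicylic acid defence genes were spread within lines, and their list mean on exon 2 replicate 4 had a Dixon ratio of 0.977. Means were 5.37 to 5.41 on the other exon 2 arrays against 7.28, 5.33 and 5.43 against 6.89 and 7.11 in exon 1, 5.79 to 6.93 in amiNAA10 and 3.89 to 4.40 in WT. Exon 2 replicate 4 alone did not make the rise, since the HYPK lines were still 1.65 above WT without it. Harvest at another time of day (r = -0.33 of morning minus evening clock genes with defence genes over 16 group-centred arrays, permutation p = 0.364; r = -0.749 for the whole circadian clock list, permutation p adjusted over 26 relations = 0.0194, bootstrap -0.906 to -0.304) and handling or wounding before harvest (r = 0.35, permutation p = 0.304) could each contribute, and both remain open. The design gives no biological explanation of spread within a line, so none was tested.

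An array was listed when its Dixon ratio exceeded the 95% critical value for 4 samples, which happens in about 1 in 20 groups of 4 by chance; 43 of 696 groups passed against 34.8 expected, 6 of them on exon 2 replicate 4. In WT these were, on replicate 1, EXPA11 (0.848), LHCB2.1 (0.940), UBQ4 (0.861) and the 26S proteasome mean (0.883), on replicate 2, BIG (0.853), AGL8 (0.848) and the aliphatic glucosinolate mean (0.853), on replicate 3, MAP1A (0.968) and the means of autophagy (0.893) and of flowering and floral markers (0.850), and on replicate 4, CRT3 (0.845), NIT2 (0.938), EIF4G (0.926) and UBQ10 (0.857). In amiNAA10 they were, on replicate 1, AT5G64170 (0.870) and the N-terminal acetyltransferase mean (0.884), on replicate 2, the chitinase gene CHI (0.878) and AT4G24820 (0.858), on replicate 3, NAA10 (0.948), BAM5 (0.952), CRK23 (0.841), EXPB3 (0.943) and the mean of flowering and floral markers (0.868), and on replicate 4, NAA15 (0.894). In the exon 1 line they were, on replicate 1, SYP111 (0.830), ATG2 (0.883), RVE1 (0.941) and CESA4 (0.888), on replicate 2, PSBP-1 (0.917), NDA1 (0.920) and the guard cell and myrosin cell mean (0.836), and on replicate 3, LDOX (0.868). In the exon 2 line they were, on replicate 1, EXPA11 (0.846), APL (0.839) and AT5G51440 (0.871), on replicate 2, CESA4 (0.927) and the vascular mean (0.858), and on replicate 4, besides the defence mean, CER1 (0.916), RPN13 (0.846), BCS1 (0.906), Hsp70-2 (0.923) and ATMG00520 (0.895).

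Between the exon 1 and exon 2 lines 4 list means also differed by camera with the preset correlation: jasmonate response by 0.29, anthocyanin and flavonoid by -0.26, rapid stress and handling by -0.29 and guard cell and myrosin cell markers by -0.17. None of their members passed limma's test, and the smallest adjusted p was 0.698 with an estimated correlation. Fry and exact permutation called 0 lists, but at 4 arrays against 4 the latter passes after adjustment only when many lists share its smallest p. The permutation result therefore says little about these list means. Single arrays moved some of these means. Rapid stress and handling, for example, was at 5.15 on exon 2 replicate 2 against 4.27 to 4.57 on the other exon 2 arrays.

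The counts of changed probe sets were compared with splits of the same arrays. For amiNAA10 against WT 1 of 35 splits, the real one, was as large as 8549, and the highest other gave 1. For the exon 1 line 1 of 35 was as large as 5448, with 1 as the highest other, and for the exon 2 line 1 of 35 was as large as 3852, with 3 as the highest other. For both HYPK lines 1 of 100 splits, the real one, was as large as 6317, with 4577 as the highest other. That split took exon 1 replicates 1 to 3 and exon 2 replicate 4 as WT and so kept the 4 WT arrays together, and the next highest gave 3017.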

How the results depend on the processing

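The camera fit with an estimated correlation was planned, while the counts of list members without exon 2 replicate 4 were chosen only after results were seen. Under a limit of at least 2-fold the counts were 2260 in amiNAA10, 1019 in the HYPK lines, 1252 in exon 1, 800 in exon 2 and 304 between HYPK loss and amiNAA10, and at adjusted p under 0.01 they were 5553, 3388, 2645, 1409 and 1059, all smaller by construction. Only the groups compared gave 2477 in exon 2, and the cause was not tested. Camera with an estimated correlation called 0 lists in amiNAA10 and 0 in the HYPK lines. The correlation between members was estimated from the arrays, so this result was not fixed in advance. It was 0.681 for salicylic acid defence, 0.741 for unfolded protein response and 0.513 for photosynthesis, against the preset 0.01. For hypoxia response it was -0.026. With single arrays left out the exon 2 count ran from 2097 (without replicate 4) to 3932 (without replicate 1), and HYPK loss against amiNAA10 from 1387 (without amiNAA10 replicate 2), with 1496 without amiNAA10 replicate 3, to 3596 (without exon 2 replicate 4); the cause was not tested. The next counts leave out fry, exact permutation, the stricter thresholds and the estimated correlation, which ended every list call. No call of a named gene or list reversed, and 41 of 289 gene results and 5 of 52 list results changed in some fit. Fry changed further list calls in amiNAA10. It did not call the 26S proteasome (adjusted p = 0.0978), and it called lists that camera did not, such as hypoxia response (adjusted p = 0.00423). A block for replicate number gave 8359, 6185, 5301, 3720, 2 and 2777 probe sets and 14 and 13 lists, with 1 named gene weaker and 5 stronger. With the block, heat shock genes in amiNAA10 passed (adjusted p = 0.0428), and jasmonate response (0.0598) and epidermis markers (0.0682) in the HYPK lines did not. As a check of pairing, residuals of arrays sharing a number had a mean r of 0.00961 over 24 pairs and 6 of 16 arrays correlated best with their own number, so pairing was not used. Centring on array medians was void, since quantile-normalised values share them. Only summarised signal was available, without background or probe values, so low signals could not be separated from background and other summaries were not run.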

Other observations

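The tests of gene families and of the run of neighbouring loci were chosen only after the results were seen, and those of photosynthesis and unfolded protein response within genotypes before the relations were computed but after the changes of the lists against WT were seen.

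Families of receptor genes rose with the defence genes. Of 52 receptor-like protein genes (RLP) 30 rose and 1 fell in amiNAA10 (camera adjusted p = 1.50e-10, and adjusted p = 0.439 with an estimated correlation), and 27 rose and 1 fell in the HYPK lines (adjusted p = 4.00e-11, and adjusted p = 0.308 with an estimated correlation). Of 40 cysteine-rich receptor-like kinase genes (CRK) 21 rose and 1 fell in amiNAA10 and 22 rose and 1 fell in the HYPK lines (adjusted p = 5.17e-07 and 1.69e-07, and adjusted p = 0.474 and 0.476 with an estimated correlation). WRKY transcription factor genes rose in 26 and 16 of 67 cases and fell in 5 and 4 (adjusted p = 0.00588 and 0.0153, and adjusted p = 0.517 and 0.650 with an estimated correlation). Wall-loosening alpha-expansin genes (EXPA) fell in 12 and 11 of 23 cases (adjusted p = 5.84e-05 and 0.000301, and adjusted p = 0.387 and 0.308 with an estimated correlation), EXPA11 by 2.68 and 1.63 and EXPA4 by 1.99 and 1.42. In all, 246 families were tested, and camera with the preset correlation called 24, 28 and 15 in amiNAA10, in the HYPK lines and between them, with 0 at an estimated correlation.

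Some translation and organelle gene families were also called. Translation initiation factor genes (EIF) rose in 10 of 18 cases in amiNAA10 (adjusted p = 0.000168, and adjusted p = 0.405 with an estimated correlation), with EIF4G at 0.84 and EIF3A at 0.60, and 4 were lower in the HYPK lines than in amiNAA10 (adjusted p = 0.00135, and adjusted p = 0.535 with an estimated correlation). Ribosomal protein genes of the large subunit (RPL) fell in 14 of 22 cases in the HYPK lines (adjusted p = 9.14e-06, and adjusted p = 0.483 with an estimated correlation), RPL18 by 0.63. Mitochondrial-encoded probe sets rose in 36 and fell in 6 of 92 cases in amiNAA10 (adjusted p = 0.000113, and adjusted p = 0.453 with an estimated correlation), ATMG00290 by 1.21, and in the HYPK lines they were not called (26 rose, 10 fell; adjusted p = 0.0740). Compared directly, 2 were higher and 14 lower in the HYPK lines than in amiNAA10 (adjusted p = 3.40e-05, and adjusted p = 0.535 with an estimated correlation). Plastid-encoded probe sets were not called in amiNAA10 (adjusted p = 0.458). All 9 light-harvesting antenna genes of photosystem II (LHCB) fell in amiNAA10 (adjusted p = 3.01e-05, and adjusted p = 0.474 with an estimated correlation), and 3 fell in the HYPK lines (adjusted p = 0.0466, and adjusted p = 0.684 with an estimated correlation). Compared directly, 8 of the 9 were higher in the HYPK lines than in amiNAA10 (adjusted p = 1.58e-06, and adjusted p = 0.535 with an estimated correlation).

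Within genotypes, arrays with higher defence genes had lower photosynthesis genes (r = -0.86 over 16 group-centred arrays, permutation p = 0.00134, adjusted over 26 relations p = 0.00916; rho = -0.794, adjusted p = 0.0119). The relation was -0.893 without exon 2 replicate 4 and exon 1 replicate 3, the farthest arrays, and bootstrap draws ran from -0.961 to -0.661. Unfolded protein response genes rose with defence genes (r = 0.98, permutation p = 0.00012, adjusted p = 0.00312; 0.959 without the same arrays, bootstrap 0.873 to 0.996). These relations were not particular to the 2 lists, as the 26S proteasome (r = 0.932, adjusted permutation p = 0.0123), mitochondrial stress (0.816, adjusted p = 0.0193), the circadian clock (-0.749, adjusted p = 0.0194) and heat shock (0.639, adjusted p = 0.0198) also went with defence genes, and so did other lists. A shared difference between arrays in harvest or plant condition might produce all of them. For photosynthesis the strength of defence alone may leave a part unaccounted for. The HYPK lines and amiNAA10 differed by -0.14 in the mean of defence genes (0 of 27 members called by limma). They differed by 0.41 in that of photosynthesis genes (29 of 47 called, adjusted exact permutation p = 0.0105). The small defence difference depended on single arrays, such as amiNAA10 replicate 2 at 6.93 and exon 2 replicate 4 at 7.28. The other amiNAA10 arrays were at 5.79 to 6.16 and the other HYPK arrays at 5.33 to 7.11. Crossing amiNAA10 and the HYPK lines to plants that cannot accumulate salicylic acid would test whether defence accounts for the photosynthesis difference.

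The genes of UNE15, MIR841a, HTA4, AT4G13572 and AT4G13575 are 5 neighbours on chromosome 4, and all were higher in the HYPK lines than in amiNAA10 (by 1.15, 2.60, 1.63, 2.13 and 2.53). Against WT in amiNAA10 UNE15 was at -1.21, MIR841a at -1.76, AT4G13572 at -2.69 and AT4G13575 at -3.07, and HTA4 was lower too (limma adjusted p = 0.00202). Chance neighbours among unrelated called loci were set aside, since 0 of 1000 random orders held a run as long and the longest had 3. Random orders remove any likeness between neighbouring loci, so shared regulation of neighbours was not tested. Overlapping loci that read one transcript do not account for the run, as 1 of its 4 neighbouring pairs overlaps. A transgene insertion or a linked segment of another background could explain it and remains open, with 1 locus of the run, AT4G13572, lower in the HYPK lines than in WT (-0.56, limma adjusted p = 0.0384). MIR841a (0.84, adjusted p = 0.0139) and HTA4 (0.64, adjusted p = 0.0205) were higher in the HYPK lines than in WT, so part of their difference from amiNAA10 came from the HYPK lines, and AT4G13575 was at -0.54 (adjusted p = 0.0536). Sequencing the amiNAA10 line at this position would test this.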
